A study of Homo sapiens with 20 samples.

How the data were processed

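The study holds 20 libraries of MCF-7 cells, 10 of Pol II chromatin immunoprecipitation and 10 of strand-specific RNA depleted of ribosomal RNA, with 1 library per assay at each of 10 times. With 1 library per time point there are no replicates. Libraries were grouped by assay and time as the labels give them. Per the submitters' processing notes Bowtie and the build hg19 were used, with no role or version given; other details of the alignment are not given in the sources used here. The deposited Pol II density per gene is a signal made by the authors, with no statement of how it was scaled. Its values matched the mean track over the last 20% of the gene best (r from 0.975 to 0.997), and 7.70 to 9.39% of all listed genes had reads in their last 20% but a density of 0 at the times up to 160 min, and none at 640 and 1280 min. The deposited tracks hold estimated counts made by the authors, reads per window of 200 bases along each gene, with a read across 2 windows split between them, not scaled to depth. Pol II windows hold at most 200 reads. The 320 min Pol II track was not analysed here, while the density of that library was.

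The Pol II tables list 55075 genes, 25966 genes appear in some pre-mRNA track and 25131 in both. Read totals over genes are given at the head of the report, lowest at 640 min for Pol II (5.83 M) and in the untreated library for pre-mRNA (11.4 M). The common biological coefficient of variation around the fitted curves was 0.113 for Pol II reads and 0.178 for pre-mRNA. Symbols were matched to 88.4% of the Ensembl IDs with a density and 96.7% of those with pre-mRNA; a RefSeq table of GRCh38.p14 served only to match older symbols, and positions are those of the deposited tracks.

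The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Change over time was tested by an F test of a natural cubic spline of log2(minutes + 5) with 3 df, which leaves 6 residual df with 10 libraries and 5 with 9, at a Benjamini-Hochberg threshold of 0.05. Kept genes had a mean above the median of genes with any value. The unit of the densities is a signal, so limma 3.58.1 was used on log2(density + 0.204), after scaling by median of ratios (factors up to 1.38 times apart). The track reads were summed over each gene, the expected counts rounded to whole numbers, and tested by the quasi-likelihood test of edgeR 4.0.16 with trimmed mean of M values scaling. The same test of Pol II reads was added after the densities had given 0 calls, and was chosen after seeing the data. Direction is the sign of the largest departure of the fitted curve from untreated, at the sampled times. R 4.3.3, DESeq2 1.42.0, Python 3.11, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

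The 5' to 3' balance is the log2 ratio of the mean Pol II signal of the first 20% to that of the last 20% of genes of at least 5 kb, tested by limma with the same spline. Agreement is Pearson's r per gene between log2 Pol II and pre-mRNA over the times, set beside r of randomly paired genes; genes are not independent replicates, so correlations across genes are described and carry no p. Delay is the difference between the assays in log2(minutes + 5) of the largest departure of the curve, over a grid of 200 steps. Windows along genes of at least 100 kb end at 25, 50 and 100 kb.

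For the 23 gene lists camera with a correlation of 0.01 was applied at 40, 160 and 1280 min, to lists with at least 5 kept members, and repeated with a correlation estimated from the data and with fry, which asks whether the genes move together in one direction. Named genes are, per assay, the 12 largest rises and 6 largest falls among called genes with a symbol and a mean in the upper 50% of kept genes, 16 genes fixed in advance, and up to 3 genes per list with the smallest p that passed when adjusted over the list alone. Reads of Pol II carry no strand; 968 of the called genes in Pol II reads (30.0%) and 258 in pre-mRNA (8.80%) overlap another called gene. In pre-mRNA 120 genes held 168 windows with over 50 times the reads of the gene's other windows, with 6.96% of all reads in the untreated library, at most 7.64% (20 min) and at least 1.21% (640 min); one alternative leaves them out.

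Alternatives changed 1 choice at a time, with the following exceptions. The fit to the untreated to 160 min libraries also lowered the spline to 2 df. The track means set in place of the densities come from 9 libraries and may cover another part of the gene. The agreement with reads for genes passing both count tests changed the genes, the Pol II measure and the libraries together. The delay with the last 20% also changed the genes compared. The choices were scaling (total, upper quartile, DESeq2 size factors), filter, pseudocount, 2 or 4 df, time as rank, limma-voom, trended variance, the DESeq2 likelihood ratio test, parts of the gene, baseline, gene length, and leaving out each library. DESeq2 size factors for pre-mRNA, scaling by mean signal, the untreated to 160 min libraries with 2 df, windows left out, genes passing both count tests, the time of 50% of the extreme and the last 20% in the delay were chosen after seeing the data. So were the genes of the delay and of the windows along long genes, since they rest on the Pol II reads test. The tests were tested on simulated data in which 200 genes changed. Of changes of 2-fold and 4-fold the Pol II reads test found 88% and 100%, with 17 unchanged genes called (8.29% of calls); the pre-mRNA test found 55% and 94%, with 15 (9.15%); the density test found 8% and 47%, with 4 (6.67%) and 1 gene in the wrong direction. A simulated delay of 1.77 was returned as 2.21, so the curve overstated it.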

Results

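MCF-7 cells, a breast cancer line that grows in response to estrogen, were kept for 72 h in medium with hormone-stripped serum and then given 10 nM 17β-estradiol, the main natural ligand of the estrogen receptor. Cells were collected untreated and at 9 times after the hormone, the first at 5 min and each later one at double the time before it, up to 1280 min. At each of these 10 times 1 library measured RNA polymerase II (Pol II) on DNA by chromatin immunoprecipitation and sequencing, and 1 library measured pre-mRNA, the unspliced transcript, from total RNA depleted of ribosomal RNA. The design asks how quickly and for how long transcription and its product respond to estradiol, and how the 2 signals follow each other along genes. The Pol II tracks used here held 27.2 M reads (M for 1000000) over genes in the untreated library and 31.3, 30.2, 26.2, 33.4, 38.3, 25.6, 5.83 and 14.0 M at 5, 10, 20, 40, 80, 160, 640 and 1280 min. The 320 min track was not analysed here. The pre-mRNA tracks held 11.4 M reads in the untreated library and 15.7, 13.3, 17.8, 17.5, 23, 19.6, 17.2, 16.4 and 18.6 M at the successive times. Changes are given on the log2 scale against the untreated library, as the largest departure of the fitted time curve, with its standard error after the ± sign and adjusted p for any change over time. Positions are those of hg19.

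Pol II rose within minutes on the best-known estrogen-induced genes, and on several of them it stayed high for the whole course. GREB1 (ENSG00000196208, chromosome 2, 11674242 to 11782914), a cofactor of the estrogen receptor, went from 77 CPM (reads per 1000000 after scaling) to 226 at 5 min and 668 at 1280 min, a rise of 2.81 ± 0.27 (9 libraries, adjusted p = 2.8e-04). PGR (ENSG00000082175, chromosome 11, 100900355 to 101001255), the progesterone receptor gene, rose by 2.41 ± 0.18 and went from 53.2 to 315 CPM at 1280 min. P2RY2 (ENSG00000175591, chromosome 11, 72929343 to 72947397), a receptor for extracellular nucleotides, rose and came back, from 16.9 to 84.5 CPM at 20 min and 15.9 at 1280 min (2.47 ± 0.19, adjusted p = 4.4e-06). CLEC3A (ENSG00000166509, chromosome 16, 78056412 to 78100658), a C-type lectin gene, fell by 1.65 ± 0.16 and BMF (ENSG00000104081, chromosome 15, 40380091 to 40401093), which promotes cell death, fell by 1.5 ± 0.16.

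These values come from reads summed over each gene in the 9 Pol II tracks, a test added after the per-gene densities gave no call. Of 26551 genes tested, 3226 changed over time (12.2%), of which 2299 rose and 927 fell, and 633 of the rises and 160 of the falls were larger than 1 on the log2 scale. With upper-quartile scaling 2130 genes rose and 1413 fell, so that 60.1% of the changes were rises against 71.3%. That scaling put the median of all genes at -0.10 at 1280 min. The fitted curve reached its extreme at 5 to 40 min for 706 of the rising genes, at 80 to 320 min for 158 and at 640 or 1280 min for 1435. By 1280 min, 549 of the rising genes (23.9%) and 333 of the falling genes (35.9%) had come back to under 50% of their extreme.

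The deposited per-gene Pol II densities, the measure chosen first, gave 0 calls among 25680 genes with limma, while 3487 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0526. With a trended prior variance limma called 25 genes, and among the 25% of genes with the highest mean it called 190. Of the 48 estrogen-induced genes with a density, 27 rose and 1 fell when adjusted over the list alone, and of the 26 estrogen-repressed genes 2 rose and 7 fell.

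The largest early Pol II rise of the well-expressed genes was on KCNK6 (ENSG00000099337, chromosome 19, 38810482 to 38819640), a potassium channel gene, which went from 9.75 CPM to 75.2 at 10 min (2.89 ± 0.32). GPR132, a G protein-coupled receptor gene, rose by 2.65 ± 0.21, ANXA9, an annexin gene, by 2.61 ± 0.24, and CXXC5, a zinc finger gene, by 2.10 ± 0.20, all 3 with the extreme at 20 min. SFXN2, a mitochondrial carrier gene, rose by 2.60 ± 0.28 with the extreme at 1280 min. RET (ENSG00000165731, chromosome 10, 43572475 to 43625799), a receptor tyrosine kinase gene, rose by 2.19 ± 0.17, from 33.9 CPM to 169 at 80 min. Rises on COL18A1-AS2 (2.77 ± 0.29), COL18A1-AS1 (2.28 ± 0.23) and VASN (2.20 ± 0.25) cannot be given to 1 gene, because Pol II reads carry no strand and these lie within COL18A1 or CORO7. That limit also holds for FKBP4, ELF3, EGR3 and NRIP1, named below, where another gene covers over 20% of the length. GRHL3, a transcription factor of surface epithelia, fell by 1.98 ± 0.30, ST3GAL1, a sialyltransferase gene, by 1.88 ± 0.21, and LMCD1 by 1.59 ± 0.18. ALDH1A3-AS1 fell by 1.52 ± 0.21 inside ALDH1A3.

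Among the other genes fixed for naming, TFF1 (ENSG00000160182, chromosome 21, 43782391 to 43786703), a secreted trefoil peptide gene, rose by 1.74 ± 0.31 in Pol II, IGFBP4 by 2.01 ± 0.33, CA12 by 1.69 ± 0.17, SIAH2 by 1.34 ± 0.19, NRIP1 by 1.25 ± 0.16 and CXCL12 by 0.78 ± 0.16. CCND1, which drives entry into the cell cycle, rose by 1.02 ± 0.19, RARA by 1.16 ± 0.20 and XBP1 by 1.04 ± 0.26. These 3 calls ended without the 5 min library (adjusted p = 0.0561, 0.0556 and 0.0956), and that of XBP1 also without the 20 min library (0.0604) or the 640 min library (0.0602). STC2 rose by 0.84 ± 0.21, and its call ended without the 5 min library (0.0847) or the 640 min library (0.0644). MYC did not pass (0.99 ± 0.25, adjusted p = 0.0599). Its Pol II reads went from 95.2 CPM to 169 at 20 min, 107 at 80 min and 199 at 640 min, the library with fewest reads. The scaled densities of MYC did not show that late maximum. They were 12.6 untreated, 25.7 at 20 min, 17.3 at 80 min and 18.0 at 640 min. ESR1, the estrogen receptor gene itself, did not pass either (-0.45 ± 0.20, adjusted p = 0.0923). Its densities had the other sign and did not pass either (0.70 ± 0.24 at 20 min, limma adjusted p = 0.357). They were 1.70 untreated, 2.99 at 20 min and 2.64 at 1280 min, so its direction in Pol II stays open.

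Of the 50 estrogen-induced genes tested, 42 rose and none fell in Pol II (46 and 0 adjusted over the list alone), and 8 did not pass. Their median change was 0.84 at 40 min, and this was the only list call that held with an estimated correlation (adjusted p = 0.0252). At 160 min the median was 0.65 and at 1280 min 0.96, with adjusted p = 0.0530 and 0.237 with an estimated correlation. Of the 29 estrogen-repressed genes 7 rose and 9 fell (9 and 12 adjusted over the list alone). TGFB2 fell by 1.43 ± 0.16 and SMAD3 by 0.68 ± 0.17, both members of the transforming growth factor beta pathway. The list's median was -0.19 at 40 min, -0.40 at 160 min and 0.15 at 1280 min (adjusted p = 0.904 and 0.201 at 40 and 160 min with an estimated correlation; not called at 1280 min). Of the 26 genes of the receptor and its cofactors 11 rose and 1 fell (11 and 3 adjusted over the list alone). At 160 min their test pointed up with a mean of 0.19 while the median was -0.0030 (adjusted p = 0.70 with an estimated correlation). Of the 35 immediate early genes 14 rose and 4 fell (17 and 7 adjusted over the list alone). Every call among the 5 named here ended without 1 library. These were FOS (0.99 ± 0.27, adjusted p = 0.0987 without 5 min, 0.0509 without 20 min and 0.0736 without 640 min), EGR3 (1.28 ± 0.32, 0.0590 without 5 min and 0.0531 without 640 min), NR4A1 (0.87 ± 0.31, 0.0519 without 640 min), FOSL2 (0.58 ± 0.15, 0.0505 without 5 min and 0.0775 without 20 min) and TRIB1 (-0.84 ± 0.19, 0.0804 without 1280 min).

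Many mitosis genes, and fewer of the replication genes, rose in Pol II late in the course. Of 51 mitosis genes 37 rose and 1 fell (43 and 2 adjusted over the list alone), among them KIF20A (1.09 ± 0.25), a kinesin of cytokinesis, CDC25C (0.95 ± 0.17), the phosphatase that starts mitosis, and INCENP (0.95 ± 0.19). Of 55 replication genes 24 rose and 1 fell (38 and 2 adjusted over the list alone), among them MYBL2 (1.01 ± 0.17), CDC45 (0.76 ± 0.25) and CDC25A (0.65 ± 0.17). The list medians at 1280 min were 0.73 and 0.59, and both calls were lost with an estimated correlation (adjusted p = 0.461 each). At 40 min the median of the mitosis genes was -0.12, a call that ended without the 40 min library (adjusted p = 0.174) or the 80 min library (0.0569) and with an estimated correlation (0.904).

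Some of the genes that make and process RNA and ribosomes rose in Pol II, and most did not pass. Of 76 genes of cytoplasmic ribosomal proteins 23 rose and none fell (50 and 0 adjusted over the list alone), with medians of 0.32 at 160 min and 0.51 at 1280 min (adjusted p = 0.70 and 0.461 with an estimated correlation). RPL41 rose by 1.01 ± 0.26 and RPS27 by 1.12 ± 0.30, the latter call ending without the 5 min library (adjusted p = 0.0549). Of 49 ribosome biogenesis genes 10 rose and 4 fell (20 and 11 adjusted over the list alone). NOLC1, a nucleolar phosphoprotein, rose by 0.74 ± 0.19 and DDX21, a nucleolar helicase, by 0.73 ± 0.18, both with the extreme at 160 min, where the list's median was 0.33 (adjusted p = 0.70 with an estimated correlation). At 1280 min that list's median was 0.06, and upper-quartile or signal-dependent scaling turned its sign (-0.03 and -0.0030). Of 56 splicing factors 17 rose and none fell (24 and 0 adjusted over the list alone), among them U2AF2 (0.70 ± 0.17) and HNRNPA2B1 (0.72 ± 0.18), with a median of 0.45 at 1280 min (adjusted p = 0.461 with an estimated correlation).

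Metabolic and stress genes moved in both directions. Of 29 genes of amino acid supply 5 rose and 7 fell (6 and 10 adjusted over the list alone). SLC7A5, an amino acid transporter, rose by 0.98 ± 0.14 with the extreme at 80 min, while SLC7A11, the cystine transporter, fell by 1.03 ± 0.18 and MTHFD1L, of mitochondrial folate metabolism, by 0.81 ± 0.17. Of 29 genes of cholesterol and lipid synthesis 11 rose and 3 fell (14 and 4 adjusted over the list alone), with DHCR7 at 1.05 ± 0.17 and INSIG1 at 0.82 ± 0.24. Their median at 1280 min was 0.46 and that of the heat shock genes 0.44 (adjusted p = 0.461 for both with an estimated correlation). Of 30 genes of hypoxia and glycolysis 4 rose and 2 fell (5 and 3 adjusted over the list alone), with HK1 at 1.06 ± 0.16 and PFKFB3 at 1.04 ± 0.19, both at 20 min. Of 22 heat shock genes 8 rose and none fell (12 and 1 adjusted over the list alone), with FKBP4, a cochaperone of steroid receptors, at 1.5 ± 0.22 and HSPB1 at 1.40 ± 0.35. Of 29 genes of the unfolded protein response 8 rose and 4 fell (11 and 5 adjusted over the list alone). Of 39 genes of oxidative phosphorylation 3 rose and none fell (3 and 0), of 27 p53 targets 3 rose and 4 fell (5 and 5), and of 18 inflammatory genes 2 rose and 3 fell (3 and 3). Of 31 interferon-stimulated genes 1 rose and none fell, and none passed when adjusted over the list alone.

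Of 26 luminal epithelial markers 15 rose and 1 fell in Pol II (19 and 4 adjusted over the list alone), among them TFAP2C (1.11 ± 0.21), ELF3 (0.91 ± 0.19) and GATA3 (0.88 ± 0.26), transcription factors of luminal cells. GATA3 had stood at -0.81 at 40 min. Their median at 1280 min was 0.65 (adjusted p = 0.461 with an estimated correlation). Of 16 basal markers 2 rose and 2 fell (6 and 5 adjusted over the list alone), with FOXC1 at 1.93 ± 0.27 and SNAI2 at -1.18 ± 0.29. Of 17 fibroblast markers 1 rose and 1 fell (2 and 5). Of 14 leukocyte markers 1 rose and 1 fell (1 and 2), and of 10 endothelial markers none passed over all genes (3 and 1 adjusted over the list alone).

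Beside the late rises stands a shift that goes with Pol II level. Among 2013 genes with no pre-mRNA trend, the median Pol II change at 1280 min was 0.39 in the 25% with most Pol II reads per kilobase and -0.16 in the 25% with fewest. Pol II windows hold at most 200 reads, and the 1280 min library was shallower than the untreated one (14.0 against 27.2 M reads). Whether this limit adds to the shift was not tested. The count of 3226 fell to 2054 without the untreated library, 989 without 5 min, 1487 without 20 min, 1883 without 80 min and 1281 without 1280 min, and rose to 7390 without 160 min. With the untreated to 160 min libraries and a spline of 2 df it was 152, against 1878 with 2 df and all libraries.

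Pre-mRNA of the same hormone targets rose as well, and CLEC3A and ALDH1A3, which lost Pol II, were among the largest falls. PGR rose by 2.88 ± 0.23 (10 libraries, adjusted p = 2.8e-05), from 86.5 to 660 CPM at 1280 min, and GREB1 by 2.85 ± 0.30, from 155 to 1245. MYC (ENSG00000136997, chromosome 8, 128747680 to 128753674), a transcription factor of growth, rose and returned, from 36.9 CPM to 199 at 40 min and 37.5 at 1280 min (2.41 ± 0.25). CLEC3A fell by 3.62 ± 0.24 (adjusted p = 1.0e-06), from 193 to 16.7 CPM, and ALDH1A3 (ENSG00000184254, chromosome 15, 101402129 to 101456831), a retinaldehyde dehydrogenase, by 4.08 ± 0.47, from 86.3 to 4.87.

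Of 12977 genes tested, 2964 changed over time (22.8%), with 1580 rises and 1384 falls, of which 745 and 612 were larger than 1 on the log2 scale. The extreme of the rising genes lay at 5 to 40 min for 439, at 80 to 320 min for 460 and at 640 or 1280 min for 681; for the falling genes the counts were 280, 400 and 704. By 1280 min 570 rising genes (36.1%) and 374 falling genes (27.0%) were back to under 50% of their extreme.

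SYNDIG1 (ENSG00000101463, chromosome 20, 24449835 to 24647252), a gene for a synaptic membrane protein, had the largest pre-mRNA rise of the well-expressed genes (3.48 ± 0.40), from 12.9 CPM to 152 at 1280 min. RAMP3 (ENSG00000122679, chromosome 7, 45197390 to 45225901), a receptor activity-modifying protein, rose by 3.39 ± 0.29 and MYBL1 (ENSG00000185697, chromosome 8, 67474414 to 67526482), a MYB family transcription factor, by 3.19 ± 0.35. HSPB8, a small heat shock protein, rose from 14.7 CPM to 127 at 40 min and stood at 16.3 at 1280 min (2.88 ± 0.39). LINC01016 rose by 2.94 ± 0.39, FMN1 by 2.69 ± 0.45, RAB31 by 2.59 ± 0.39, SYTL4 by 2.51 ± 0.24 and VASN, within CORO7, by 2.77 ± 0.62. LHX4 rose by 2.83 ± 0.65, a call that ended without the 5, 10, 20 or 40 min library (adjusted p = 0.105, 0.0757, 0.0653 and 0.0509). NTN4, a laminin-related gene, fell by 3.52 ± 0.37, CLIP4 by 3.44 ± 0.55 and ADCY5, an adenylate cyclase, by 3.26 ± 0.68. ADCY5 stood above untreated at 80 min, with 444 of 11.4 M reads untreated, 2072 of 23 M at 80 min and 87 of 18.6 M at 1280 min. The fall of 3.26 ± 0.97 at MYO1D rested on reads piled up in 2 windows of 200 bases and was not there without them (adjusted p = 0.338), nor past the threshold without the 10 min library (0.0524).

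CXCL12, a chemokine gene, rose by 3.51 ± 0.33, from 2.97 to 32.4 CPM at 160 min. IGFBP4 rose by 2.50 ± 0.30, TFF1 by 2.32 ± 0.34, CA12 by 1.94 ± 0.38, SIAH2 by 1.75 ± 0.35, NRIP1 by 1.33 ± 0.25, RARA by 1.17 ± 0.20 and STC2 by 0.73 ± 0.15. FOS rose by 3.53 ± 0.70 on few reads, 8 in the untreated library and 98 at 40 min. XBP1 rose by 0.91 ± 0.20, a call that ended without the 20 min library (adjusted p = 0.0649). CCND1 (0.65 ± 0.21, adjusted p = 0.0670) and ESR1 (0.43 ± 0.22, adjusted p = 0.107) did not pass, and EGR3 had too few pre-mRNA reads to be tested.

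**Figure D1:**
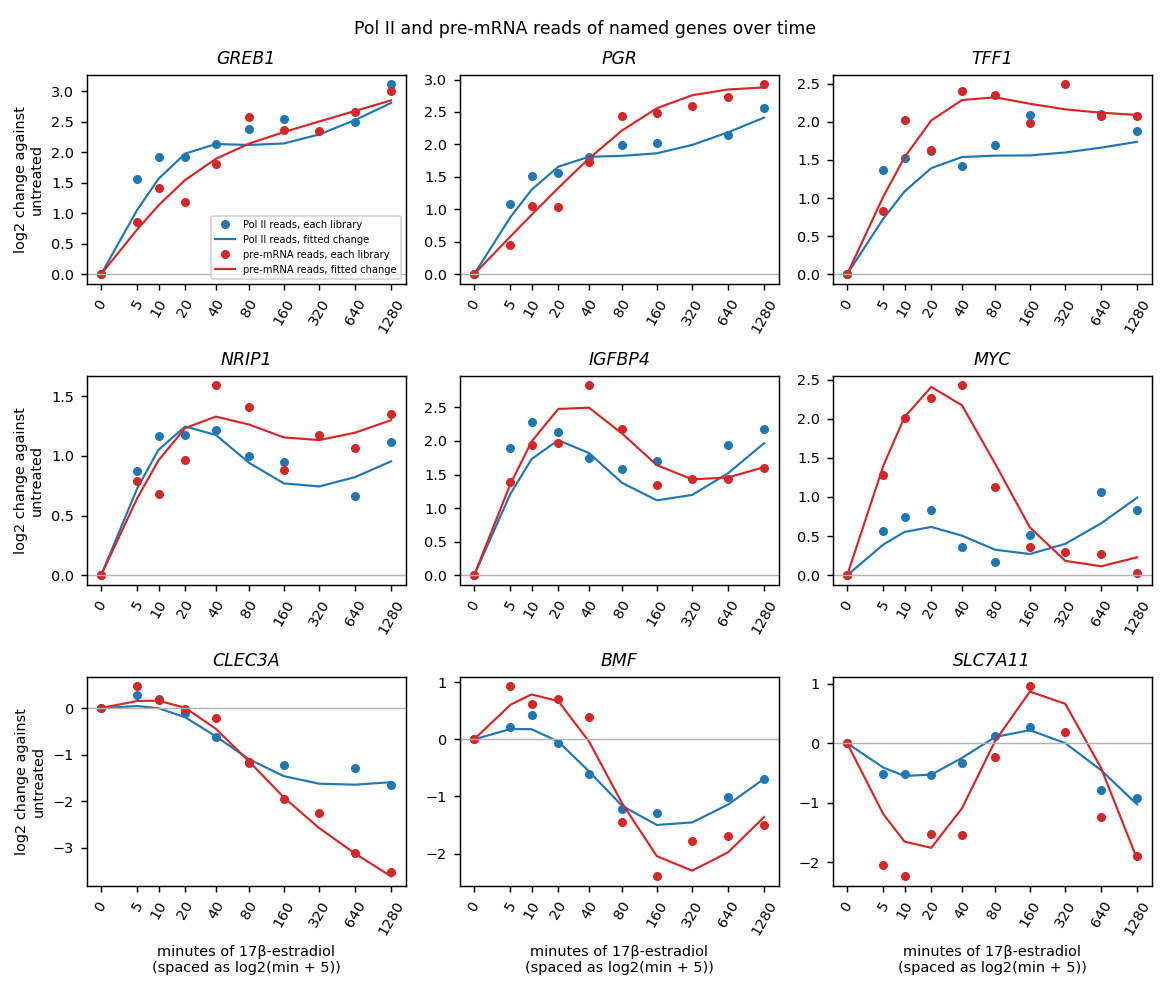
Log2 change of reads against the untreated library (y axis) over minutes of estradiol (x axis, spaced as log2 of minutes plus 5) for 9 named genes; points are single libraries and lines the fitted curves, blue for Pol II and red for pre-mRNA. GREB1 and PGR stay high to 1280 min in both, MYC pre-mRNA peaks near 20 to 40 min, and CLEC3A falls further in pre-mRNA (3.62 lower) than in Pol II (1.65 lower).

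Of 44 estrogen-induced genes with enough pre-mRNA 30 rose and 1 fell (36 and 1 adjusted over the list alone), with medians of 1.28, 1.23 and 0.83 at 40, 160 and 1280 min (adjusted p = 0.0682, 0.143 and 0.419 with an estimated correlation). Of 26 estrogen-repressed genes 18 fell and 5 rose, with the same counts adjusted over the list alone. BMF fell by 2.30 ± 0.28 and BAMBI, a decoy receptor for transforming growth factor beta, by 1.1 ± 0.14, whereas HES1, a Notch target, rose by 2.30 ± 0.41 at 20 min. BMF and BAMBI were first above untreated. BAMBI had 1068 of 11.4 M reads untreated, 3047 of 17.8 M at 20 min and 831 of 16.4 M at 640 min. BMF had 347 reads untreated, 878 of 15.7 M at 5 min and 116 of 19.6 M at 160 min. This list's median was -0.91 at 160 min (adjusted p = 0.223 with an estimated correlation). Of 22 immediate early genes 6 rose and 4 fell (9 and 5 adjusted over the list alone). KLF10 rose by 2.44 ± 0.37. The median was 0.46 at 40 min and -0.43 at 1280 min (adjusted p = 0.469 and 0.452 with an estimated correlation). Of 26 receptor and cofactor genes 7 rose and 3 fell, with the same counts adjusted over the list alone.

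Many mitosis genes rose in pre-mRNA as well, while most replication genes did not pass. Of 51 mitosis genes 36 rose and 6 fell (38 and 8 adjusted over the list alone), among them TPX2 (1.43 ± 0.25), KIF4A (1.28 ± 0.21) and CDCA8 (0.87 ± 0.20). Their median was -0.28 at 160 min, a call that ended without the 80 min library (adjusted p = 0.0788), and 1.03 at 1280 min (adjusted p = 0.973 and 0.419 with an estimated correlation). Of 54 replication genes 21 rose and 2 fell (23 and 3 adjusted over the list alone), with DSCC1 at 1.16 ± 0.30 and POLA1 at 0.63 ± 0.18, while MCM6 fell by 0.55 ± 0.18 at 20 min and stood 0.58 above untreated at 160 min. The median was 0.64 at 1280 min (adjusted p = 0.444 with an estimated correlation).

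Among the genes that make ribosomes falls in pre-mRNA outnumbered rises, though many did not pass. Of 45 ribosome biogenesis genes 23 fell and 1 rose (29 and 1 adjusted over the list alone), with medians of -0.31 at 40 min, 0.19 at 160 min and -0.80 at 1280 min (adjusted p = 0.749 at 40 min and 0.440 at 1280 min with an estimated correlation). DDX21 fell by 1.44 ± 0.29, UTP20 by 1.15 ± 0.29 and LTV1 by 0.97 ± 0.25, all at 1280 min. DDX21 stood at 214 CPM untreated, 114 at 5 min, 250 at 80 min and 79.4 at 1280 min. Of 62 ribosomal protein genes 22 fell and none rose (24 and 1 adjusted over the list alone), with RPS12 at -0.82 ± 0.16 and RPL37 at -0.53 ± 0.20 and medians of -0.33 at 40 min, 0.01 at 160 min and -0.50 at 1280 min (adjusted p = 0.469 at 40 min and 0.419 at 1280 min with an estimated correlation). The difference between the assays was not tested for these lists. With a spline of 2 df these 1280 min calls ended (adjusted p = 0.372 and 0.650), and that of ribosome biogenesis at 40 min turned to up (0.0410). Of 54 splicing factors 2 rose and 2 fell, and none passed when adjusted over the list alone.

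Of 27 genes of amino acid supply 9 fell and 4 rose (14 and 4 adjusted over the list alone), with SLC7A11 at -1.95 ± 0.43, MTHFD1L at -1.02 ± 0.22 and PHGDH, of serine synthesis, at -0.97 ± 0.27. Their median was -0.62 at 1280 min (adjusted p = 0.440 with an estimated correlation). SLC7A11 stood above untreated at 160 min, with 707 of 11.4 M reads untreated and 2441 of 19.6 M at 160 min. So did MTHFD1L (3963 and 9744 reads) and PHGDH (456 and 1451 reads). Of 27 genes of cholesterol and lipid synthesis 5 fell and none rose (10 and 2 adjusted over the list alone), with DHCR24 at -1.11 ± 0.19, INSIG1 at -0.91 ± 0.19 and FASN at -0.76 ± 0.17. The fall of INSIG1 was not kept, with 1109 of 11.4 M reads untreated, 853 of 17.5 M at 40 min and 2065 of 18.6 M at 1280 min. Its Pol II reads likewise were 790 of 27.2 M untreated, 573 of 33.4 M at 40 min and 751 of 14.0 M at 1280 min. Of 26 p53 targets 5 fell and 1 rose, with the same counts adjusted over the list alone, among them GDF15 (-2.67 ± 0.44) and PLK2 (-1.61 ± 0.26). Both were first above the untreated library. GDF15 went from 14.5 to 32.5 at 10 min and 2.27 at 1280 min, and PLK2 from 39.9 to 59.6 at 10 min and 13.7 at 320 min. TP53INP1 is counted as a fall by its fitted curve (-1.24 ± 0.30), but no library reached that value. The largest observed departure was a rise, from 32.3 CPM to 86.7 at 5 min, and the lowest library stood at 18.8 CPM (80 min). Of 10 inflammatory genes 2 rose and 2 fell (2 and 3 adjusted over the list alone). IRF1 rose by 2.24 ± 0.53 and BCL3 by 0.90 ± 0.24 at 20 min. The rise of IRF1 rested on few reads, 11 in the untreated library and 74 at 20 min. RELB fell by 3.98 ± 0.79, a call that ended without the 10 min library (adjusted p = 0.0564). The fall of RELB was not steady, with 465 of 11.4 M reads untreated and 125 of 15.7 M at 5 min. It stood above untreated at 80 min (1280 of 23 M) and had 57 of 18.6 M at 1280 min. Of 23 genes of hypoxia and glycolysis 6 rose and 3 fell (9 and 6), with NDRG1 at 1.81 ± 0.42, HK2 at 0.97 ± 0.18 and PDK1 at 0.53 ± 0.17. Of 31 genes of oxidative phosphorylation 1 rose and 3 fell (1 and 1), with COX7A2 at -0.96 ± 0.19 and NDUFB5 at 0.93 ± 0.24. Of 16 heat shock genes 1 rose and 4 fell (1 and 4), of 26 genes of the unfolded protein response 2 rose and 2 fell (1 and 2), and of 14 interferon-stimulated genes 1 rose and none fell, with none past the threshold adjusted over the list alone.

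Of 23 luminal markers 7 rose and 3 fell in pre-mRNA, with the same counts adjusted over the list alone. The keratin gene KRT8 rose by 0.95 ± 0.18 and KRT19 by 0.65 ± 0.20, both at 20 min, and KRT18 fell by 0.89 ± 0.16 at 320 min. KRT18 was also first above untreated, with 719 of 11.4 M reads untreated and 1841 of 17.8 M at 20 min. KRT8 was later below untreated, with 2613 of 11.4 M reads untreated and 3229 of 17.2 M at 320 min. KRT8 and KRT18 thus differ in which departure was larger. Of 11 basal markers 1 rose and 5 fell (2 and 7), with CAV2 at 0.97 ± 0.24 and TP63 at -1.71 ± 0.36. Of 5 fibroblast markers 1 rose and 2 fell (2 and 3), with FBLN1 at 2.06 ± 0.46 and COL3A1 at -2.20 ± 0.61. Of 3 leukocyte markers FCGR3A fell (-2.48 ± 0.49), a call that ended when its window of piled-up reads was left out (adjusted p = 0.170). Of 4 endothelial markers VWF rose (2.95 ± 1.02), a call that ended without the 40 min library (adjusted p = 0.0567).

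Between neighbouring pre-mRNA libraries 923 genes differed by over 1 on the log2 scale from untreated to 5 min, against 416 from 5 to 10 min and 380 from 10 to 20 min, but 1271 did from 40 to 80 min. The count of 2964 was 2740 without the untreated library and fell to 1784 without the 5 min library, 1674 without 10 min and 1718 without 20 min, to 1854 among the 25% of genes with the highest mean, to 779 for reads of the last 20% of each gene and to 273 with the untreated to 160 min libraries and a spline of 2 df, against 834 with 2 df and all libraries.

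**Figure D2:**
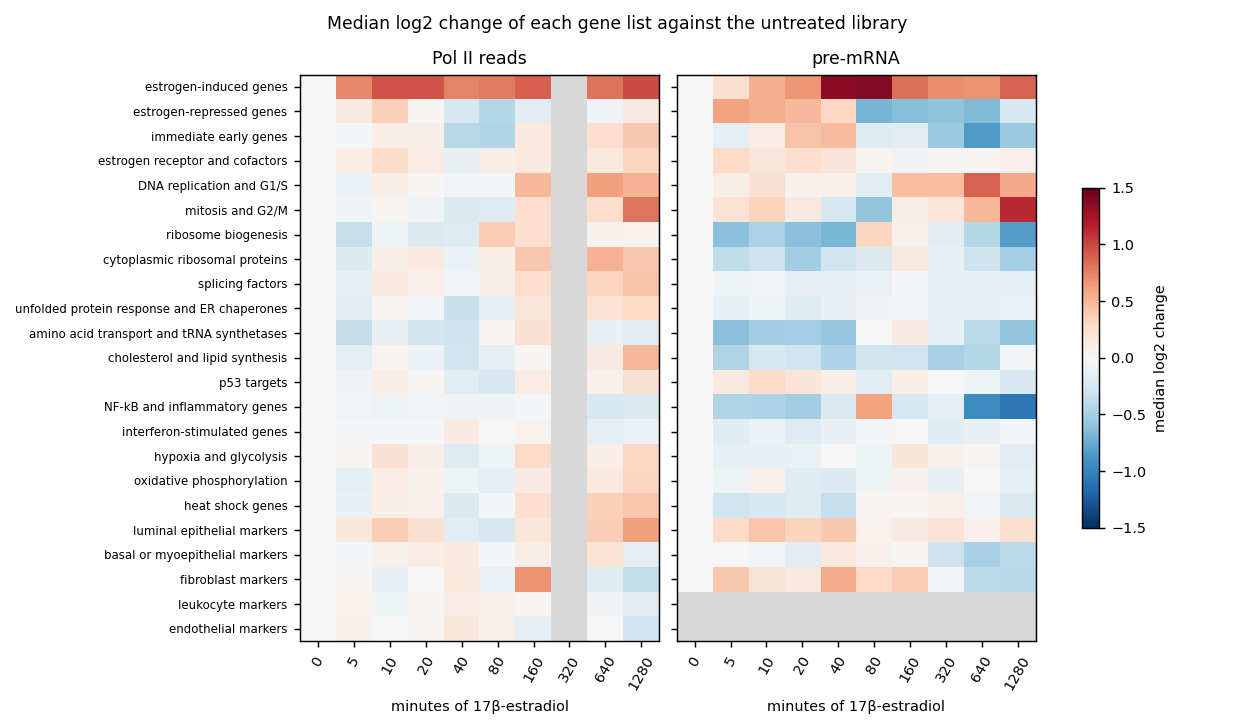
Median log2 change against the untreated library (colour) of each gene list (lines of the map) at each time in minutes (columns), for Pol II reads and pre-mRNA; grey marks the 320 min Pol II library and lists with under 5 genes. Estrogen-induced genes are raised at all treated times in both panels, and mitosis genes reach their highest median at 1280 min in both (fitted medians 0.73 and 1.03).

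Few genes passed the test for a shift of Pol II between the start and the end of the gene, and the estrogen-induced genes with the widest swings were not among them. GREB1 had 0.71 on the log2 scale for the Pol II signal of its first 20% over that of its last 20% in the untreated library, 2.44 at 20 min and 0.94 at 80 min (fitted change 1.55 ± 0.32, 9 libraries, adjusted p = 0.0967). CA12 had 0.80 untreated, 2.60 at 5 min and 0.04 at 80 min (-1.32 ± 0.57, adjusted p = 0.176). Of 14939 genes of at least 5 kb, limma called 2, chosen for naming after their values were seen. BRI3BP (ENSG00000184992, chromosome 12, 125478246 to 125515684) shifted toward its start by 1.24 ± 0.14, with the extreme at 20 min, and FAM174B (ENSG00000185442, chromosome 15, 93160673 to 93353114) by 0.99 ± 0.18 with the extreme at 1280 min (adjusted p = 0.0232 for both). In all, 2896 genes had an unadjusted p under 0.05. Both calls rest on single libraries and on the setting: the count was 0 without any 1 of the untreated to 160 min libraries, 24 without 640 min and 804 without 1280 min, 611 for the first 2 kb against the rest and 0 for the first against the last 10%.

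Pol II and pre-mRNA followed each other over time on the genes that changed. The Pearson correlation between the 2 signals over the 9 shared tracks was 0.937 for GREB1, 0.922 for PGR, 0.877 for CXCL12 and 0.817 for TFF1. It was -0.474 for FOS, -0.375 for STC2 and -0.140 for XBP1. Whether the limit of 200 reads per Pol II window bears on these negative values was not tested. Across the 883 genes that passed both count tests the median was 0.751 and 95.6% of the genes were positive, against a median of -0.0423 when genes were paired at random. Across all 10598 genes kept in both assays, with the densities at 10 times, the median was 0.337 (quartiles 0.0345 and 0.606), against 0.00733 for random pairs. With Pol II of the preceding time it was 0.180. Of 12748 genes tested in both assays 431 rose in both, 2.22 times the 194 expected if the calls were independent, and 267 fell in both, 4.46 times the 59.9 expected. In 128 genes Pol II rose and pre-mRNA fell (168 expected), and in 57 Pol II fell and pre-mRNA rose (69.0 expected).

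Of 12 genes fixed for naming, the pre-mRNA curve peaked after that of Pol II in 5, before it in 5 and at the same time in 2. These times lie on fitted curves between widely spaced libraries, so delays under 1 doubling of time are not read as a shift. Among the 5 later genes only CA12 went beyond that (1.69). The delay was 0.68 for NRIP1, 0.93 for SIAH2, 0.40 for IGFBP4 and 0.36 for RARA. NRIP1 peaked at 23.2 min in Pol II and 40.3 min in pre-mRNA, SIAH2 at 20.9 and 44.2 min, CA12 at 22.4 and 83.4 min, IGFBP4 at 20.9 and 29.2 min and RARA at 18.8 and 25.6 min. On the fitted curves TFF1, STC2, XBP1, FOS and CXCL12 went the other way. They were highest at 1280 min in Pol II and at 63.8, 122, 24.8, 20.2 and 416 min in pre-mRNA. In the densities the fitted extreme of TFF1 lay at 80 min. Pol II windows hold at most 200 reads, and FOS, 3457 bases long, held 2860 reads at 10 min. Reads of such genes may be held down in the deeper libraries up to 160 min. Their late Pol II peaks may therefore follow depth, which was not tested. GREB1 and PGR were highest at 1280 min in both, and first reached 50% of their extreme at 8.27 and 8.64 min in Pol II and 16.3 and 24.0 min in pre-mRNA. Over the 698 genes that passed both tests in the same direction the median delay was 0, with pre-mRNA later by at least 1 doubling of time in 128 (18.3%) and earlier in 80 (11.5%). The delay went with gene length at a Spearman rho of -0.188 across these genes. Among the 431 rising genes alone rho was 0.209, with longer genes later, and among the 267 falling genes it was -0.622. When the delay was taken at 50% of the extreme its median was 0.241 and rho was -0.0238.

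On long induced genes the Pol II rise was largest near the start at 5 to 20 min and was smaller, but present, farther along. In 159 risen genes of at least 100 kb, among them GREB1, NRIP1 and PGR, the median change over the first 25 kb was 0.43 at 5 min, highest at 10 min (0.56) and down to 0.33 at 40 min and 0.19 at 80 min. From 25 to 50 kb the median was highest at 40 min (0.42), from 50 to 100 kb at 80 min (0.36), and beyond 100 kb at 80 min (0.35). The far windows were already raised at 10 min, at 0.25 from 50 to 100 kb and 0.24 beyond 100 kb, where the medians at 20 and 40 min were lower (0.17 and 0.15). In the 80 risen genes of at least 150 kb the peaks lay at 20 min for the first 25 kb (0.55) and for 25 to 50 kb (0.38), at 40 min for 50 to 100 kb (0.32, with 0.25 at 80 min) and at 80 min beyond 100 kb (0.41). In pre-mRNA of 148 of these genes the first 25 kb were highest at 40 min (1.16), and the windows from 25 to 50 kb (1.11), 50 to 100 kb (1.04) and beyond 100 kb (0.82) at 80 min, when the 25 to 50 kb window of long genes that did not pass also had its highest median (0.27). Among 3823 other long genes no Pol II window had a median outside -0.19 to 0.07. The genes were chosen for a rise in the same Pol II reads, so the rise itself is not tested here, and neither is the order of the windows in time. With the mean of the untreated and 5 min libraries as the baseline, the first 25 kb had 0.18 at 40 min and -0.01 at 160 min, against 0.13 at 160 min.

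**Figure D3:**
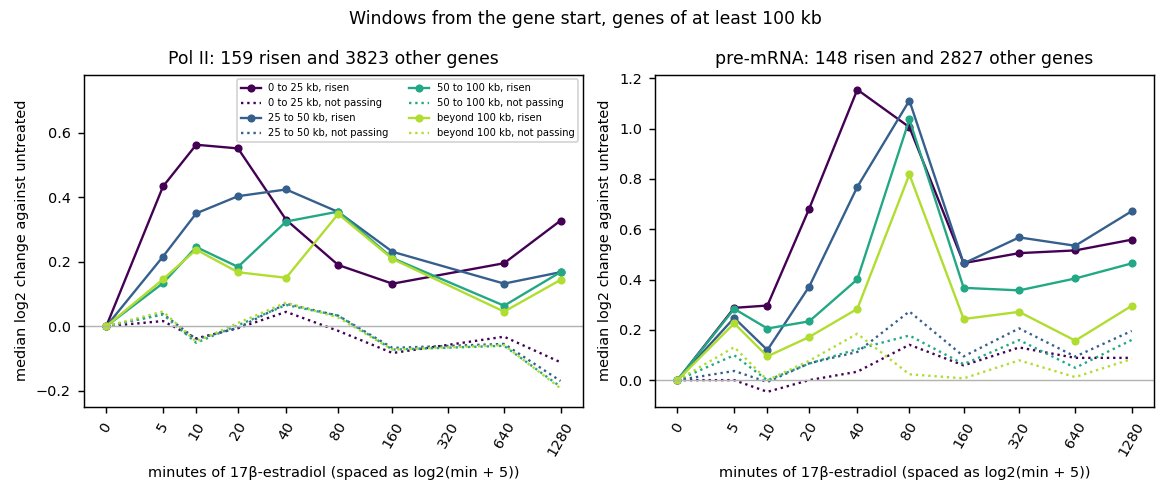
Median log2 change against the untreated library (y axis) over minutes of estradiol (x axis, spaced as log2 of minutes plus 5) in windows counted from the gene start, for genes of at least 100 kb; solid lines are genes risen in Pol II, dotted lines genes that did not pass. In the Pol II panel the window nearest the start peaks at 10 min (0.56) and the window beyond 100 kb at 80 min (0.35).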

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

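The patterns below were seen first, and each test of them was chosen after the pattern was seen, with its prediction written before the test was run. Intervals in this part are over genes, which are not independent replicates, and hold no spread between libraries.

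Pol II reads were higher at 1280 min than in the untreated library in many groups of expressed genes, such as ribosomal proteins (median 0.51) and splicing factors (0.45). If the immunoprecipitation had enriched genes over background more at 1280 min, genes with more Pol II would rise more even without a pre-mRNA trend, and among 2013 such genes the top 25% by Pol II lay 0.549 above the bottom 25% (95% interval 0.491 to 0.601). If transcription had risen, Pol II and pre-mRNA changes would go together, and across 642 late-rising genes r was 0.461 (0.398 to 0.520), with a median pre-mRNA change of 0.09 against 0.76 in Pol II. Scaling by mean signal left the 2 list medians at 0.45 and 0.43 and kept all 31 list calls, though it follows mean reads and not reads per kilobase and had no prediction written for it. Neither explanation is ruled out, so part of the late rises may be enrichment, and how much stays open, since no input or spiked-in chromatin was used here. Depth is a further limit, since Pol II windows hold at most 200 reads. The tracks up to 160 min held 25.6 to 38.3 M reads, against 5.83 and 14.0 M at 640 and 1280 min. Genes dense in Pol II may be held down in the deeper libraries and so seem to rise late, which was not tested.

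The Pol II library at 640 min lay farther from the fitted curves than the others, with a residual SD of the densities of 0.595 against 0.203 to 0.412. Over the SD that the fit leads to at each time, the 1280 min library stood apart almost as much (1.37 at 640 min and 1.31 at 1280 min, against 0.846 to 0.940). The 10 genes with most reads held 1.59% at 640 min and 1.58 to 1.76% elsewhere, but windows hold at most 200 reads in every track, so this cannot tell whether a few genes took most of the reads. The thinning used track reads of the last 20% of each gene and not the densities. In these reads the SD of log2 160 min minus 80 min was 0.502. Thinning the 160 min track to the depth of the 640 min track brought this SD to 0.763. That is 0.853 of the SD of 1280 min minus 640 min (0.894). Low depth could thus account for much of the spread of these reads. Only the 160 min track was thinned, and the 80 min track (38.3 M reads) was deeper than the 1280 min track (14.0 M). Reads summed over the whole gene were not tested in this way. Genes with reads but a density of 0 made up 7.70 to 9.39% up to 160 min and 0% at 640 and 1280 min. The densities of these late libraries may thus have been made in another way, which was not tested. The SD of 1280 min minus 640 min holds both late libraries, so which of them stands apart stays open.

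From untreated to 5 min 923 of 12977 genes differed over 2-fold in pre-mRNA, 423 lower and 500 higher, more than in the next 2 steps (416 and 380) but fewer than from 40 to 80 min (1271). Pol II changed with pre-mRNA over the same 5 min (r = 0.447, 0.393 to 0.498, 897 genes), which is consistent with transcription changing within 5 min. Few reads per gene also remains possible, since 34.6% of these genes had at least 50 reads in both libraries. A length bias could not be told either way: the median length was 25325 bases for the lower and 44087 for the higher genes, 1.74-fold apart. Whether the hormone, the handling of the cells or the single untreated library made the difference stays open, because the labels give 1 untreated library per assay.

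Random orders of the libraries over the times gave fewer calls than the real order in every case. For pre-mRNA the real order gave 2964 genes and the highest of the other orders 415, and 1 of 100 orders, the real one, reached the real count. For Pol II reads the real order gave 3226 genes and the highest of the other orders 1870, again with 1 of 100 reaching the real count. Chance order thus did not reach either count among the orders drawn, and with this number a share below 1 of 100 cannot be seen. The margin was smaller for Pol II reads, a test chosen after the densities had given no call.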

How the results depend on the processing

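Alternatives chosen only after the data were seen were the whole test of Pol II reads with its alternatives, the untreated to 160 min libraries with 2 df, scaling by mean signal, DESeq2 size factors for pre-mRNA, windows left out, the genes passing both count tests, the time of 50% of the extreme, the last 20% in the delay, and the genes of the delay and of the long-gene windows. No paired analysis was possible because each assay had 1 library per time point. Unless said otherwise, the cause was not tested.

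The density test stayed at 0 calls in most settings and with any library left out (0 to 0). It gave 190 among the 25% of genes with the highest mean, where fewer genes were tested, 85 with 5 times the pseudocount, 25 with a trended variance and 363 with the track mean of the whole gene, which changed the source, the libraries (9) and the part of the gene together. Its 18 list calls became 0 with an estimated correlation and 3 with fry (15 to 19 without 1 library).

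The 3226 calls in Pol II reads moved to 1878 with 2 df, 5179 with rank of time, 5496 with the DESeq2 likelihood ratio, 1595 with the last 20% of the gene and 152 with the untreated to 160 min libraries and 2 df, which changed 2 choices together. Without 1 library the range was 989 to 7390, with 2054 (untreated), 989 (5 min), 1487 (20 min), 1883 (80 min), 7390 (160 min) and 1281 (1280 min) beyond 1.5 times. Scalings gave 3097 to 4122. The 31 list calls became 1 with an estimated correlation and 2 with fry, and 27 to 34 without 1 library. The call of the immediate early genes at 160 min reversed from down to up with 4 df (adjusted p = 0.0188).

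The 2964 pre-mRNA calls moved to 1854 with the upper 25% of genes, 834 with 2 df, 779 with the last 20% and 273 with the untreated to 160 min libraries and 2 df, again 2 choices together. Without 1 library the range was 1674 to 3955, with 1784 (5 min), 1674 (10 min) and 1718 (20 min) beyond 1.5 times. Scalings gave 2974 to 3100, and windows of extreme depth left out 2995. The 26 list calls became 0 with an estimated correlation, 8 with fry and 17 with 2 df, and 22 to 27 without 1 library. The call of ribosome biogenesis at 40 min reversed from down to up with 2 df (adjusted p = 0.0410). Leaving out 1 library ended a call of 26 named genes in Pol II reads and 13 in pre-mRNA, and reversed none.

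The balance count of 2 became 0 with 10% at each end, 611 with the first 2 kb, 0 with 0.1 of the pseudocount, 54 with 5 times it, and 0 to 804 without 1 library (24 without 640 min).

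The median r of 0.337 moved to 0.180 with Pol II of the preceding time and lay between 0.298 and 0.365 without 1 library. For the genes passing both count tests it was 0.740 with densities and 0.751 with reads. The latter used 883 genes and 9 times against 10598 genes and 10 times, so genes, measure and libraries changed together. The median delay stayed 0 without any 1 library and was 0.241 at 50% of the extreme; genes with both curves highest at 1280 min have a delay of 0 by construction. Its rho with length (-0.188) reversed to 0.209 in rising genes alone and moved to -0.0238 at 50% of the extreme, with -0.209 to -0.135 without 1 library. With untreated and 5 min as the baseline the first 25 kb moved to 0.18 at 40 min and reversed to -0.0117 at 160 min, and 25 to 50 kb moved to 0.31 and 0.12; the 5 min rise is then part of the baseline by construction. In genes of at least 150 kb the 25 to 50 kb window was highest at 20 min (0.38) and the 50 to 100 kb window at 40 min (0.32).

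Without the untreated library there was no direction, gene, list or delay value. Depth limits the 640 min Pol II library (5.83 M reads) and pre-mRNA of short genes such as FOS (8 reads untreated).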

Other observations

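Which genes are named in this part was chosen after their values were seen; the test of the aryl hydrocarbon receptor targets was chosen after their fall in pre-mRNA was seen, with its prediction written before it was run.

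Some single genes stood far from the untreated library in pre-mRNA 5 min after the hormone, in both directions. CREBRF, a regulator of metabolic stress, was at 9.36 CPM untreated and 49.2 CPM at 5 min (107 and 746 reads), HBP1, a repressor of the cell cycle, went from 420 to 2227 reads and KLHL24 from 242 to 1281. VCL, which links adhesions to actin, went from 5600 to 2073 reads, SLC7A11 from 707 to 226 and PRUNE2 from 493 to 82. PRUNE2 had no passing trend over the whole course.

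Genes induced by the aryl hydrocarbon receptor, a sensor of foreign compounds, were mixed, and several of those that fell were lower in pre-mRNA from the first treated library on. Of 6 kept in pre-mRNA 5 fell: CYP1B1 by 2.79, AHRR by 2.13, NQO1 by 1.2, ALDH1A3 by 4.08 and CYP1A1, which ended near 0 reads (23.4 CPM untreated, 0.0529 at 1280 min, adjusted p = 6.8e-04). TIPARP did not pass (0.25 at 1280 min), though it went from 189 CPM untreated to 449 at 40 min and 202 at 1280 min. Much of the drop was there at 5 min for CYP1B1 (89.1 to 25.3 CPM), ALDH1A3 (86.3 to 27.0) and CYP1A1 (23.4 to 2.17), and Pol II of these 3 genes was lower at 5 min too (134 to 96.0, 86.5 to 55.0 and 8.65 to 4.58 CPM); AHRR (70.8 to 72.6) and NQO1 (99.5 to 88.2) fell later. In Pol II reads CYP1A1 fell by 2.01, ALDH1A3 by 1.48, CYP1B1 by 1.44, UGT1A6 by 0.93 and AHRR by 0.74, while TIPARP, which is also induced by estradiol, rose by 0.72 with the extreme at 40 min. NQO1 (0.10 at 1280 min), CYP1A2 (-0.02) and ALDH3A1 (-0.30) did not pass.

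The hypothesis was that these genes lose transcription, so that Pol II falls on them too. The median Pol II change at 1280 min over the 9 genes kept was -0.738, with 5 of them called fallen, which is in line with lost transcription but leans on the same kind of comparison with 1 untreated library. The labels give no untreated library at the later times, so time in culture and estradiol cannot be told apart as the cause.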
